A study of Mus musculus with 9 samples.

How the data were processed

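Retinal RNA was isolated with a Qiagen column kit, and 1.3 ug of total RNA went into each SMARTER library, per the labels. The authors deposited one table of FPKM values, by their name fragment counts scaled by transcript length and library depth, for 35397 genes and 9 samples. The genome build is mm10, per the submitters' processing notes. The aligner, the counter, the strand of counting and the annotation are not given in the sources used here. The table's columns are named Control or DR with a number. Each was matched to the wild-type or db/db sample with that number, which is an inference from the names. Groups came from the sample titles. Symbols, positions and biotypes came from GENCODE M21, which uses the same assembly, for 34499 of the 35397 identifiers.

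The depth was read from the values. FPKM multiplied by the union exon length of GENCODE M21 moved in steps of a constant per library, so that between 98.9% and 99.1% of low values were whole within 0.1 read. The recovered depth was 36.6 to 47.9 M reads per library. Of the low whole values 59.8% (wild type 2) to 63.1% (db/db 5) were even numbers, so a read counted here need not be a separate fragment. At that depth 1 FPKM over 1 kb of exon stands for 36.6 to 47.9 reads.

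Values were tested as log2(FPKM + 1), so fold changes of low genes are understated. Genes with a mean of at least 1 FPKM over the 9 libraries were kept (14588). Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with db/db against wild type and no covariate. Adjusted p-values are Benjamini-Hochberg over all kept genes, with a threshold of 0.05. The gene lists, 19 of pathways and 19 of cell types, the rule for naming genes and the first group of alternatives below were fixed before the data were examined. The 36 with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 36 lists. Camera with an estimated correlation and fry were run beside it. Within each list, p-values were also adjusted over the list alone. For Bcat1 an exact two-sided permutation test over the 126 regroupings was run, whose smallest possible p is 0.00794. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

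The rule for naming genes took the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, leaving out symbols that join Gm, LOC, AC, AL or BC to a number, Rik names and names with a -ps suffix. Other clone names, such as CT025671.2, were not left out. It added Bcat1, Bcat2 and Lepr, up to 4 members of each list past the threshold or else the 2 with the smallest p, and Xist, 4 Y-linked genes and Nnt. Lepr, Xist and Nnt fell below the filter, and their values came from a fit without it. Some genes that the rule named are not reported here. Other genes named were chosen after their values were seen.

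The steps were tested on simulated data with 200 of 14588 genes changed. With all 9 libraries 55% of genes changed by 0.5 on the log2 scale and 85% of those changed by 1 were recovered, with 6 unchanged genes called. Without db/db 1 the shares were 81% and 98%, with 8 unchanged genes called. Camera gave a p under 0.05 for 2% of unmoved lists in both. Genes were drawn independently, each with the same SD in all libraries. The simulation thus held neither correlation between genes nor an outlying library, and these shares do not give the error rate or recovery in the real libraries.

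The alternatives fixed in advance were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, eBayes without a trend, robust eBayes, median-of-ratios scaling, scaling to equal sums, quantile normalization, array weights, the replicate number as a block, and leaving out each library in turn. Those chosen after seeing the data were leaving out db/db 1 and db/db 4 together, median correction per library in 20 bins of transcript GC content or length, both corrections together, GC correction without db/db 1, and limma-voom on the recovered reads. GC content and length were those of the longest annotated transcript, known for 99.3% of tested genes. No 2 libraries held the same values, and none was left out of the comparison. The same tests were run on 100 of the 126 splits of the 9 libraries into groups of 5 and 4, the real one included, and on the 56 splits of the 8 libraries without db/db 1. Values far from the rest of their group were sought with Dixon's ratio at 0.829 for 4 samples and 0.71 for 5.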

Results

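RNA was sequenced from retinas of wild-type mice and of db/db mice, a strain that lacks a working leptin receptor and becomes obese and diabetic. The set held 5 wild-type libraries and 4 db/db libraries, named here by the numbers in their labels (wild type 1 to 5, and db/db 1, 3, 4 and 5). Expression was given as FPKM for 35397 genes, of which 14588 reached a mean of 1 FPKM and were tested. The reads recovered from the FPKM steps came to between 36.6 M in db/db 5 and 47.9 M in wild type 1. The labels name neither litters nor batches, nor do they say whether each library came from a separate animal, so p-values measure the spread between these libraries. Xist was listed at 0.0967 ± 0.0218 FPKM (SD, n = 5) in wild type and 0.0878 ± 0.00550 FPKM (SD, n = 4) in db/db. The Y-linked genes Eif2s3y (14.7 FPKM in db/db 5, the lowest), Ddx3y, Kdm5d and Uty were expressed in all 9 libraries. Nnt, a mitochondrial transhydrogenase gene, stood at 0.0376 FPKM in wild type and 0.00394 FPKM in db/db.

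The comparison of db/db with wild type asked which genes differ in the diabetic retina. The clearest rise was that of Selenbp1, which encodes a selenium-binding protein with methanethiol oxidase activity (ENSMUSG00000068874, chromosome 3, 94933056 to 94944758, mm10). It went from 6.87 ± 2.01 FPKM (SD, n = 5) in wild type to 28.0 ± 2.99 FPKM (SD, n = 4) in db/db, a 4.07-fold ratio of means, with a log2 change of 1.91 (SE 0.18, limma adjusted p = 0.00829; 0.00297 to 0.0443 over 25 alternatives). Its neighbour and close paralog Selenbp2 rose by 1.10 (adjusted p = 0.0104), and reads may have been shared between the pair. Stard4, a carrier of cholesterol within cells, fell from 4.47 ± 0.261 FPKM (SD, n = 5) to 2.77 ± 0.0969 FPKM (SD, n = 4), a log2 change of -0.53 (SE 0.06, adjusted p = 0.0115). Insig1, a sterol sensor, fell by 0.47 (adjusted p = 0.0420), and Hsp90b1, a chaperone of the endoplasmic reticulum, fell by 0.45 (adjusted p = 0.0419).

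In all, 34 genes were higher and 39 lower in db/db at an adjusted p under 0.05, and 2810 genes had an unadjusted p under 0.05. In none of the 73 did the 9 values overlap between the groups, which selection on the same values makes likely. Such separation occurred in 11.6% of all tested genes, where chance gives 1.59%. Genes move together, so the excess does not count independent separations. Ranked on log2(FPKM + 1), among symbols that the naming rule admits, the next largest rises were those of Scn4a, the skeletal muscle sodium channel (log2 change 0.82), the pseudogene CT025671.2 (0.71), the proton channel gene Otop3 (0.64), Rhbdf2 (0.60), Begain (0.57), Nt5dc2 (0.54), the kinase gene Pim1 (0.48) and Fam129b (0.48). On that scale the largest falls among such symbols were in Katnal2, a microtubule-severing protein gene (-0.66), Ttc14 (-0.64), the ciliary gene Ccdc39 (-0.63), Gckr, the glucokinase regulator (-0.57), Stard4 (-0.53), the nuclear export receptor gene Xpo1 (-0.52), Col20a1 (-0.52), Tnfsf13 (-0.51), the glycine receptor gene Glra3 (-0.51) and Slc22a29 (-0.48). By the ratio of mean FPKM the order differs, with Slc22a29 (0.513) and Ccdc39 (0.563) lower than Katnal2 (0.570), and CT025671.2 (2.38) higher than Scn4a (2.03). Some predicted or noncoding genes that the rule leaves out moved further, such as BC055402 (1.23), Gm7665 (0.89), Gm25321 (-1.01) and Gm28439 (-0.91), named after their values were seen. Ttc14 and Ccdc39 overlap on opposite strands, as do Fam129b and Lrsam1 and Tnfsf13 and Tnfsf13os, and since the strand of counting is not given their reads may not be fully separate. Col20a1 is overlapped on its own strand by BX649560.1 (mean 5.58 FPKM), and Hsp90b1 by Gm15344 (mean 6.08 FPKM). Reads of these pairs may be shared whatever the strand of counting. The adjusted p of the 73 genes lay between 0.00829 and 0.0494. After scaling to equal sums 21 were higher and 15 lower, so that 58.3% of the calls were higher in db/db against 46.6% in the comparison as reported.

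The count of calls depended on single libraries. Without db/db 1, 688 genes were higher and 852 lower, and these included all 73 genes, each in its direction. Without db/db 1 and db/db 4 together, the genes higher in db/db numbered 289 and the genes lower in db/db 254. The counts of higher and lower genes fell to 4 and 2 without wild type 1, 3 and 1 without wild type 2, and 4 and 1 without wild type 3, wild type 4 or wild type 5. They were 3 and 1 without db/db 3, 8 and 5 without db/db 4, and 4 and 5 without db/db 5. Selenbp1, the long noncoding BC055402 (log2 change 1.23) and Gm49096 (-0.73) passed in each of the 9 fits that left out 1 library; the last 2 were named after their values were seen. Of the 22 named genes past the threshold, 22 passed when db/db 1 was left out, 5 without db/db 4, 4 without db/db 5, 3 without wild type 1, and 2 without each of wild type 2, 3, 4 and 5 and db/db 3. Over all 24 alternatives the log2 change of Scn4a ran from 0.71 to 0.99 and that of Katnal2 from -0.83 to -0.58. That of Glra3 varied more, from -0.73 to -0.25. With the replicate number as a block, although the numbers do not pair the samples, the adjusted p of Stard4, Insig1 and Hsp90b1 reached 0.428 and that of Selenbp2 0.289, while their log2 changes hardly moved. After correction for GC content 5 genes were higher and 1 lower with all 9 libraries, and after correction for transcript length 270 and 243. With the GC correction and db/db 1 left out, 374 genes were higher and 341 lower, and 68 of the 73 genes were among them. Of the named genes not past the threshold with all 9 libraries, 34 passed with db/db 1 left out and 14 with the GC correction as well.

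**Figure D1:**
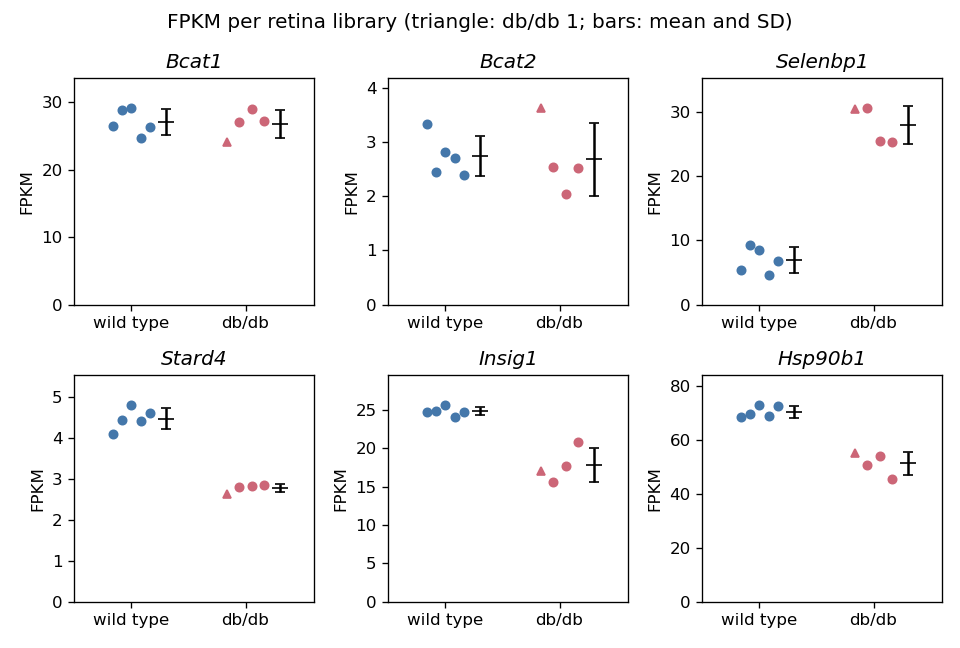
FPKM (vertical axis, from 0) of 6 genes in each retina library, with wild type in blue and db/db in red; the triangle is db/db 1, and the black bars give the mean and SD of 5 wild-type and 4 db/db libraries. Bcat1 and Bcat2 overlap between the groups, while Selenbp1 is higher and Stard4, Insig1 and Hsp90b1 are lower in each of the 4 db/db libraries than in any wild-type library.

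The series title names BCAT1, the cytosolic enzyme that transfers the amino group of branched-chain amino acids. Bcat1 (ENSMUSG00000030268, chromosome 6, 144993835 to 145076184) showed no difference beyond the spread between libraries, at 27.1 ± 1.89 FPKM (SD, n = 5) in wild type and 26.8 ± 2.07 FPKM (SD, n = 4) in db/db. Its log2 change was -0.01 (SE 0.07, adjusted p = 0.929, exact two-sided permutation p = 0.897), with a 95% interval of 0.882 to 1.11 for the fold. Its sign varied over 26 alternatives, from -0.09 to 0.12, and its adjusted p ran from 0.397 to 0.980. The mitochondrial isoform gene Bcat2 stood at 2.74 ± 0.373 FPKM (SD, n = 5) and 2.68 ± 0.672 FPKM (SD, n = 4), with a log2 change of -0.04 (adjusted p = 0.893). The annotation places the antisense genes Gm26666 and Gm15687 within Bcat1, so some of its reads may belong to them. Lepr, mutated in db/db, was listed at 0.0387 FPKM in wild type and 0.0504 FPKM in db/db, below the filter. A gene total of this kind does not check the db splice mutation.

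None of the 29 measured genes of branched-chain amino acid catabolism and transport rose or fell over all genes tested. Adjusted over the list alone, 1 was higher and 1 lower. These were Bckdk, the kinase that turns off the branched-chain ketoacid dehydrogenase (log2 change 0.31, adjusted p over all genes = 0.0735), and Mut, the methylmalonyl-CoA mutase gene (-0.37, adjusted p = 0.0692). The list as a whole was not called by camera (adjusted p = 0.813), and its median of -0.02 and mean of 0.01 differed in sign. With db/db 1 left out 3 of its members rose and 2 fell, Bckdk (adjusted p = 0.0312) and Mut (-0.29, adjusted p = 0.0160) among them. With the GC correction as well, Bckdk passed (adjusted p = 0.0422) and Mut did not (-0.17, adjusted p = 0.0606). The camera adjusted p of the list was 0.733 with db/db 1 left out, and 0.403 to 0.980 over 26 alternatives.

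Inflammation is also named in the title. Of 11 measured cytokine, chemokine and NF-kB target genes of 39 fixed, none rose or fell over all genes, and 1 was higher adjusted over the list alone. That gene was Nfkbia, the NF-kB inhibitor, at 14.4 ± 1.71 FPKM (SD, n = 5) and 19.95 ± 2.07 FPKM (SD, n = 4), with a log2 change of 0.45 (adjusted p over all genes = 0.0735; 0.0309 without db/db 1, and 0.0555 with the GC correction as well). Cxcl16 had 0.15 (adjusted p = 0.313). Without db/db 1, Nfkbia rose and 1 other member of the list fell over all genes. With all 9 libraries the camera adjusted p of the list was 0.664, with a median of -0.0023 against a mean of 0.04. The remaining genes of this list, most cytokines among them, lay below the filter and were not tested. None of 13 interferon-stimulated genes passed over all genes (camera adjusted p = 0.935), and adjusted over the list alone Ifi35 was higher (0.38) while Ifit2 had -0.22 without passing. Complement genes, 8 measured, were not called (adjusted p = 0.883), with Cd59a at -0.32 (adjusted p = 0.276) and Serping1 at 0.22 (adjusted p = 0.538). With db/db 1 left out 2 complement genes fell, Cd59a among them (-0.49, adjusted p = 0.0127; 0.0345 with the GC correction as well). The median of the complement list was 0.0030 and its test pointed down, while that of the interferon list was -0.0076 and its test pointed up.

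Among metabolic lists, genes of cholesterol and fatty acid synthesis were called lower, but not with an estimated correlation (adjusted p = 0.473). Of 22 measured members 1 fell over all genes (Insig1) and 21 did not pass, while adjusted over the list alone 10 were lower and 1 higher. Idi1, Sqle and Scd1, which act in isoprenoid synthesis, squalene epoxidation and unsaturated fatty acid synthesis, had log2 changes of -0.50, -0.31 and -0.49. Their adjusted p over all genes were 0.0537, 0.0735 and 0.0615, and Srebf1 had a log2 change of 0.32 (adjusted p = 0.128). The median was -0.20 (camera adjusted p = 6.85e-05; fry adjusted p = 0.0644). The camera adjusted p was 0.0158 without db/db 1, where 7 members fell and 1 rose, and 6.45e-07 to 0.473 over 26 alternatives. Without db/db 1 fry gave an adjusted p of 0.0430, while camera with an estimated correlation gave 0.923. In 7 of 100 splits of the 9 libraries the camera p of this list was as small as in the real one.

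Genes of the mitochondrial genome were called lower, and nuclear genes of oxidative phosphorylation higher, but neither with an estimated correlation (adjusted p = 0.962 for each). In 15 and 64 of 100 splits of the 9 libraries their camera p was as small as in the real one. None of 13 mitochondrial-genome transcripts passed over all genes, and 4 were lower adjusted over the list alone. These included the complex I subunit genes mt-Nd5 (2104 FPKM in wild type and 1337 FPKM in db/db, log2 change -0.67, adjusted p over all genes = 0.0563) and mt-Nd2 (-0.74, adjusted p = 0.0822). The median was -0.39 (camera adjusted p = 6.51e-04; fry adjusted p = 0.285), and -0.54 without db/db 1, where 7 members fell. The mean of the list relative to wild type was -0.06 in db/db 1, within the wild-type range of -0.09 to 0.15, and -0.22, -0.64 and -0.83 in db/db 3, 4 and 5. These stand in the order of the libraries' correlations with GC content (0.23, 0.29, 0.46 and 0.67). Without db/db 1 an estimated correlation gave an adjusted p of 0.923. At the preset correlation the list stayed called after GC correction, with all 9 libraries and without db/db 1. In the latter fit mt-Nd5 moved from -0.56 to -0.37 and mt-Nd2 from -0.88 to -0.69, and both passed over all genes (adjusted p = 0.0300 and 0.0239). Quantile normalization ended this call and that of the nuclear genes (adjusted p = 0.0784 for each), and the adjusted p of the mitochondrial list ran from 3.87e-07 to 0.962 over 26 alternatives. None of 30 nuclear-encoded oxidative phosphorylation genes passed, with Sdha at 0.22 (adjusted p = 0.0849) and Atp5a1 at 0.21 (adjusted p = 0.205). Their median was 0.19 (camera adjusted p = 0.00379; fry adjusted p = 0.754), and the call was lost with array weights (adjusted p = 0.728), without db/db 1 and db/db 4 (0.0817), with the GC correction and db/db 1 left out (0.841) and without db/db 1 (0.813; 5.73e-05 to 0.962 over 26 alternatives). Glycolysis (23 measured, adjusted p = 0.664, Slc2a1 0.19 and Aldoc 0.22), the hypoxia response (20 measured, adjusted p = 0.652, Ero1l -0.42 and Ndrg1 0.27) and antioxidant and NRF2 target genes (22 measured, adjusted p = 0.260, Nqo1 0.54 and Gclm -0.24) were not called, and no member passed over all genes. Adjusted over the list alone, 3 antioxidant genes were higher and 1 lower.

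Immediate-early genes were called higher as a list, but not with an estimated correlation (adjusted p = 0.962), and none of 15 passed over all genes. In 12 of 100 splits the camera p was as small. Adjusted over the list alone 1 was higher, Dusp1, a phosphatase gene induced by stress (0.39, adjusted p over all genes = 0.0735). Its reads may not be fully separate from those of Ergic1 (mean 10.3 FPKM), which overlaps it on the opposite strand. Ier2 had 0.57 (adjusted p = 0.118). The median was 0.26 (camera adjusted p = 0.00379; fry adjusted p = 0.188), and the call was lost with correction for GC content and length (adjusted p = 0.0541), without db/db 1 and db/db 4 (0.0729), and with the GC correction and db/db 1 left out (0.188; 7.51e-04 to 0.962 over 26 alternatives). Of 23 genes of the unfolded protein and integrated stress response Hsp90b1 fell and 22 did not pass, with 2 lower adjusted over the list alone (camera adjusted p = 0.883, pointing up, while fry pointed down). No member passed in the other lists, and none of these was called: heat shock and protein folding (adjusted p = 0.724, Hspa1a 0.57 and its near-identical copy Hspa1b 0.51), the circadian clock (adjusted p = 0.908, Arntl 0.29), 2-oxoglutarate-dependent demethylases (adjusted p = 0.249, Kdm7a -0.19 and Tet1 -0.17) and extracellular matrix (adjusted p = 0.664, Tgfb2 -0.20 and Sparc 0.30). The same held for histone and DNA methyltransferases (adjusted p = 0.724), angiogenesis (adjusted p = 0.652, Fgf2 -0.34 and Thbs1 0.57) and glial stress (adjusted p = 0.287, A2m 0.40). Ehmt2, which methylates histone H3, and Suv39h1 had 0.34 and 0.29 (adjusted p over all genes = 0.0526 and 0.0868), and they were the 2 methyltransferase genes higher adjusted over the list alone. The mean of the methyltransferase list was -0.43 in db/db 1 and 0.05, 0.12 and -0.0014 in db/db 3, 4 and 5. Leaving out db/db 1 turned its median from -0.09 to 0.04, with 6 of 25 members higher and 0 lower, and that of demethylases from -0.10 to 0.03. In the angiogenesis list 4 of 14 members then rose and 1 fell (fry adjusted p = 0.0430), but camera did not call it (adjusted p = 0.134; 0.923 with an estimated correlation). The cholesterol and fatty acid synthesis list and the horizontal cell list had the same fry adjusted p in that fit. The counts adjusted over the list alone were 2 higher for heat shock, 3 higher for the clock, 1 higher and 1 lower for angiogenesis, 1 higher and 2 lower for glial stress, and 0 for demethylases and matrix. The clock's median of -0.02 and its mean of 0.0039 differed in sign.

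**Figure D2:**
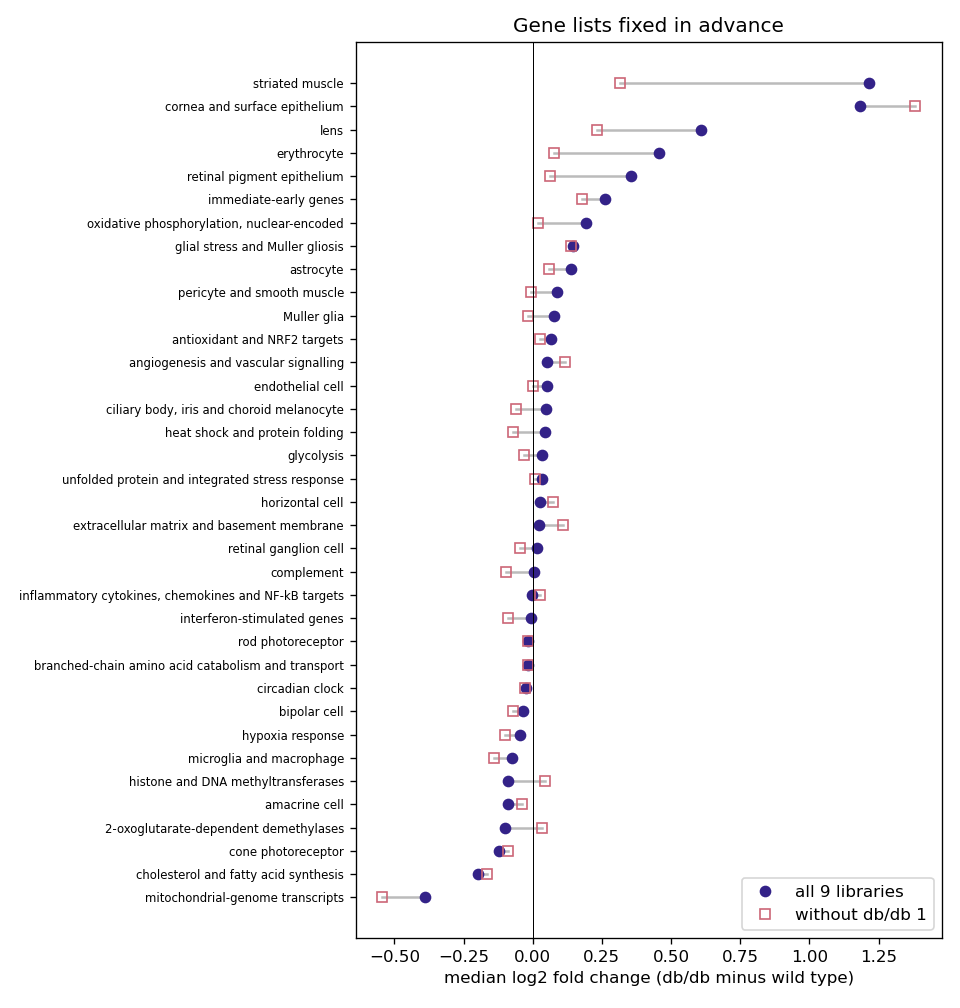
Median log2 fold change of the measured members (horizontal axis, db/db minus wild type on log2(FPKM + 1)) of each of the 36 gene lists tested, with all 9 libraries (filled circles) and without db/db 1 (open squares). Striated muscle moves from 1.22 to 0.32 and nuclear-encoded oxidative phosphorylation from 0.19 to 0.02, while mitochondrial-genome transcripts stay below 0.

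With all 9 libraries, markers of the retina's own cells were not called as lists, and none of their members passed over all genes. Bipolar cell genes became called with quantile normalization (adjusted p = 0.0215, range 0.0215 to 0.962). Microglia and macrophage genes did so with correction for GC content and length (adjusted p = 0.0156, range 0.0156 to 0.962). Both calls were at the preset correlation, and the 0.962 is the adjusted p with an estimated correlation and all 9 libraries. Rod genes had a median of -0.02 (17 measured, camera adjusted p = 0.726), with Sag, rod arrestin, at 577 ± 35.9 FPKM (SD, n = 5) and 477 ± 41.5 FPKM (SD, n = 4) and a log2 change of -0.28 (adjusted p = 0.124), and Rp1 at -0.31. Cone genes had a median of -0.12 (adjusted p = 0.268), and 2 of 12 were lower adjusted over the list alone, the channel gene Cngb3 (-0.38) and the phosphodiesterase gene Pde6c (-0.32). For bipolar cells the adjusted p was 0.249 (Vsx1 -0.26, Grik1 -0.12), for amacrine cells 0.632 (Tfap2b -0.38, Gad2 -0.29), for horizontal cells 0.406 (Sept4 0.36, Slc4a3 0.11) and for ganglion cells 0.883 (Tubb3 0.28, Sncg 0.38). Among glia, Muller cell genes (adjusted p = 0.974) included Abca8a at -0.55 and the glutamate transporter gene Slc1a3 at -0.34, both lower adjusted over the list alone, and the median of 0.08 stood against a test pointing down. Astrocyte genes had an adjusted p of 0.412 (Aldh1l1 0.32, Slc7a10 0.21) and microglia and macrophage genes 0.652 (Csf1r -0.20). In the vessel wall, pericyte and smooth muscle genes (adjusted p = 0.883) had 3 members higher and 3 lower adjusted over the list alone, among them Abcc9 (-0.40) and Rgs5 (-0.31), with a median of 0.09 and a test pointing down. Endothelial genes had an adjusted p of 0.724 (Slc2a1 0.19, Ly6c1 -0.15). Adjusted over the list alone, 1 horizontal cell gene (Sept4) and 1 astrocyte gene (Aldh1l1) were higher, and no rod, bipolar, amacrine, ganglion cell, microglia or endothelial gene passed. When db/db 1 was left out, the members higher and lower over all genes numbered 0 and 2 for rods, and 0 and 2 for cones. They were 0 and 0 for bipolar, 1 and 2 for amacrine, 2 and 0 for horizontal and 1 and 1 for ganglion cells. For Muller cells they were 1 and 3, astrocytes 1 and 0, microglia 0 and 1, endothelium 1 and 1, and pericytes and smooth muscle 2 and 3. Of the members named here, Abca8a, Slc1a3, Cngb3, Sag, Gad2, Tfap2b, Abcc9, Rgs5 and Ly6c1 fell in that fit, and Tubb3, Sept4, Aldh1l1 and Slc4a3 rose (adjusted p from 0.00614 for Abca8a to 0.0459 for Tubb3). With the GC correction as well, Abca8a (adjusted p = 0.0171), Slc1a3 (0.0456), Abcc9 (0.0374) and Sept4 (0.0232) still passed. The others did not, with adjusted p from 0.0568 for Ly6c1 to 0.165 for Cngb3. The log2 change moved little for Ly6c1 (-0.28 to -0.26) and Sag (-0.30 to -0.28) and more for Cngb3 (-0.32 to -0.18), Rgs5 (-0.36 to -0.21), Tubb3 (0.28 to 0.19), Slc4a3 (0.20 to 0.12), Gad2 (-0.19 to -0.11), Tfap2b (-0.25 to -0.19) and Aldh1l1 (0.32 to 0.26).

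Markers of tissue outside the neural retina differed between single db/db libraries, and for lens between wild-type libraries too. Relative to the wild-type mean, the mean of the lens list ran from -1.44 in wild type 3 to 1.47 in wild type 5. In db/db it ran from -1.46 in db/db 4 to 2.32 in db/db 5. Striated muscle genes were called higher (11 measured, none past the threshold, median 1.22, camera adjusted p = 0.00468; adjusted p = 0.962 with an estimated correlation; fry adjusted p = 0.589). Acta1, skeletal muscle actin, stood at 59.0 FPKM in db/db 1 and 1.06 to 1.93 FPKM in wild type. In db/db 3, 4 and 5 it stood at 2.57, 6.14 and 2.88 FPKM. The myosin gene Myh4 stood at 17.1 FPKM in db/db 1. Scn4a, outside this list, was at its lowest among db/db libraries in db/db 1 (4.65 FPKM, against 7.57, 6.73 and 7.24 FPKM in db/db 3, 4 and 5). Cornea and surface epithelium genes were called higher (8 measured, none past the threshold, median 1.18, adjusted p = 0.0235; adjusted p = 0.962 with an estimated correlation; fry adjusted p = 0.556). Aldh3a1, the corneal crystallin gene, stood at 124 FPKM in db/db 4, 11.3 FPKM in db/db 3 and 1.24 ± 0.723 FPKM (SD, n = 5) in wild type, and Perp at 13.7 FPKM in db/db 4. The cornea call was lost without wild type 4 (adjusted p = 0.0690) without db/db 4 (0.0527), without db/db 1 and db/db 4 (0.0729), and with correction for length (0.0847) or GC content and length (0.0541), with a range of 0.00248 to 0.962 over 25 alternatives. Without db/db 1 the muscle list was still called (adjusted p = 0.0352; 0.947 with an estimated correlation), and Acta1 rose (0.88, adjusted p = 0.0335; 0.0662 with the GC correction as well). The call was lost without db/db 1 and db/db 4 (adjusted p = 0.376) and with the GC correction and db/db 1 left out (0.134; 3.24e-04 to 0.962 over 25 alternatives). In 46 of 100 splits for muscle and 45 for cornea the camera p was as small as in the real one. Of the 14 muscle and 12 cornea genes fixed, 3 and 5 reached a mean of 1 FPKM in wild-type retina. The other members measured passed the filter only through their db/db values, which raises both medians, although with no filter both lists were still called. Lens (adjusted p = 0.258, Cryab 0.61, Crygc 0.92), retinal pigment epithelium (adjusted p = 0.203, Pmel 0.66, Slc6a20a 0.40), erythrocyte (adjusted p = 0.391, Hba-a1 0.62, Hba-a2 0.59) and ciliary body, iris and choroid genes (adjusted p = 0.700, Col9a1 0.43, Opcml -0.23) were not called. Lens became called without wild type 5 (adjusted p = 0.0208) or db/db 4 (adjusted p = 0.00782, range 0.00782 to 0.962). Pigment epithelium did so with correction for GC content (adjusted p = 0.0195), for GC content and length (0.0225) and without db/db 4 (0.00553, range 0.00553 to 0.962). These calls were at the preset correlation, and the 0.962 is the adjusted p with an estimated correlation and all 9 libraries. In the ciliary body list 1 gene was higher and 1 lower adjusted over the list alone, and in the other 3, muscle and cornea the count was 0. Too few genes were measured to test neutrophil and lymphocyte markers (0) or oligodendrocyte markers (4, with Mobp at -0.81, not past the threshold).

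The libraries also differed in how expression moved with transcript properties. Across 7646 protein-coding genes, which are not independent replicates, the deviation of db/db 1 from wild type had a Spearman correlation of -0.76 with transcript length, against -0.33 to 0.40 for the wild-type libraries. With GC content the correlations were 0.23, 0.29, 0.46 and 0.67 for db/db 1, 3, 4 and 5, and -0.29 to 0.25 in wild type. The median log2 change, db/db minus wild type, went from -0.11 in the quintile of genes with the lowest GC content to 0.15 in the highest, and from 0.16 in the shortest quintile to -0.11 in the longest. Leaving out db/db 1 gave -0.010 and -0.0072 for the shortest and longest, and -0.13 and 0.11 for the lowest and highest GC content. The first principal component held 54.4% of the variance and set db/db 1 apart at 58.2, with the other 8 libraries between -15.6 and -1.96. Of the 36 lists 6 were called with all 9 libraries, 5 without db/db 1, and 0 with an estimated correlation. As many lists were called in 81 of 100 splits of the 9 libraries into groups of these sizes.

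**Figure D3:**
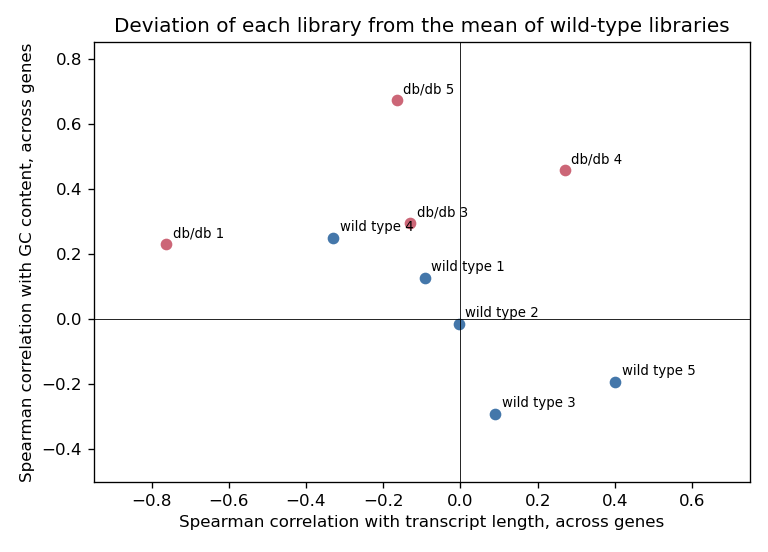
Spearman correlation, across 7646 protein-coding genes, of each library's deviation from the mean of the wild-type libraries (itself left out) with transcript length (horizontal axis) and GC content (vertical axis), with wild type in blue and db/db in red. db/db 1 lies farthest to the left at -0.76, and db/db 5 is highest at 0.67.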

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

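Among the tests below, the corrections for GC content and length, and the GC, length and dilution tests of the sterol list, were chosen only after the result was seen. A gap between the highest or lowest library and the rest of its group drew attention to 25 of 274 group values, where chance gives about 1 in 20 groups, or 13.7. Of the 25, 14 were in db/db 1 and 3 in db/db 4.

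In db/db 1 Acta1, a skeletal muscle actin gene, lay far above the other db/db libraries at 59.0 FPKM, as did the pigment cell gene Pmel at 28.4 FPKM and the globin genes Hba-a1 at 25.6 FPKM and Hba-a2 at 9.23 FPKM. The matrix gene Sparc stood at 60.3 FPKM, the endothelial gene Ly6c1 at 11.4 FPKM and the myelin gene Mobp at 1.04 FPKM, each above the rest of its group. Relative to the wild-type mean, the mean log2 value of the list in db/db 1 was the highest of its group for erythrocyte genes (1.40), antioxidant genes (0.44), the unfolded protein response (0.24) and ganglion cell genes (0.17). It was the lowest of its group for demethylases (-0.37), amacrine cell genes (-0.17) and angiogenesis genes (-0.12). In db/db 4 the corneal gene Aldh3a1 stood at 124 FPKM and Perp at 13.7 FPKM, above the rest, and Otop3 at 4.05 FPKM, below it.

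In wild type 1 Thbs1 stood at 3.57 FPKM, the cornea list had a mean of 0.59, and 28492 genes were above 0, each the highest of its group. In wild type 4 Katnal2 stood at 6.57 FPKM and Col9a1 at 17.0 FPKM, the highest, and Ifit2 at 2.82 FPKM, the lowest. In wild type 5 Mut stood at 6.15 FPKM, the highest, and nuclear oxidative phosphorylation genes had a mean of -0.070, the lowest.

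With all 9 libraries 73 genes passed, while 1540 passed without db/db 1. The real split was the 1 of 100 with as many calls, and the highest other split gave 3. That argues against chance, although 1 of 100 is the smallest share this test can give. Leaving out the 203 genes over 2 times higher in db/db 1 than in each other library gave 81 calls, but each gene is tested on its own values, so that count could hardly have moved and muscle and other foreign tissue in db/db 1 stay open. Correcting each library for transcript length gave 513 calls, but correcting for GC content as well gave 32 genes higher and 38 lower, against 5 and 1 with the GC correction alone, so a length-dependent bias in db/db 1 may account for part of the spread that kept the count low. What gave db/db 1 its length trend stays open, since the labels name no batch or RNA quality.

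Without db/db 1 the real split was the 1 of 56 with as many calls as 1540, and the highest other split gave 2. That too argues against chance, although 1 of 56 is the smallest share possible. In addition, db/db 1 was the only library whose removal alone raised the counts. GC content moved with the groups, and after its correction 715 genes still passed, against 2 in the highest other split. That argues against a trend with the GC content of the longest transcript as the whole cause. A bias of another form that moves with the groups stays open, since the other splits mix the groups. Of the 1540 genes 558 passed after correction, and for the remainder the trend may be part of the cause. The difference in genotype that the design names stays open and untested, and so does any difference in handling between the groups.

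The lower cholesterol and fatty acid synthesis list was still called after GC correction, with a camera adjusted p of 3.32e-04 as the larger of the values with and without db/db 1. It was also called without db/db 1 (adjusted p = 0.0158), which at the preset correlation argues against the length bias of that library. With an estimated correlation neither that fit (adjusted p = 0.923) nor the one with all 9 libraries (0.473) called it. Its median of -0.20 lay below the -0.02 of rod genes (one-sided permutation p over genes = 0.0118). That permutation treats genes as independent and leaves out the spread between libraries, so dilution by other tissue stays open. In 7 of 100 splits the camera p of the sterol list was as small as the real 1.90e-06, the smallest other being 2.13e-08, so chance cannot be excluded. The lists as a group fare no better, since 81 of 100 splits called as many as 6, the highest 17. A lower level of this pathway in db/db may be a hypothesis for other samples; these do not separate it from structure among the libraries.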

How the results depend on the processing

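The joint removal of db/db 1 and db/db 4, the GC and length corrections and limma-voom were chosen after seeing the data. The counts of genes higher in db/db and genes lower in db/db, 34 and 39 as reported, were 7 and 2 with no filter, 17 and 13 with a filter at 5 FPKM, 21 and 15 after scaling to equal sums, and 550 and 656 with array weights, which gave db/db 1 a weight of 0.0648. They were 289 and 254 without db/db 1 and db/db 4, 5 and 1 after GC correction, 270 and 243 after length correction, 32 and 38 after both, 374 and 341 after GC correction without db/db 1, and 46 and 64 with limma-voom. Leaving out 1 library gave 3 to 688 higher and 1 to 852 lower. The replicate number as a block gave 2 and 0, but the numbers do not pair the samples: same-number residuals correlated at 0.04, 0.05, -0.18 and 0.13, and no number was best matched with its own in both directions. Causes of these shifts were not tested beyond the tests of length, GC content and muscle genes given above. Some settings also held fewer samples or more genes tested, and the part these played was not measured.

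Of the 6 lists called, 0 were called with an estimated correlation, 2 without db/db 1 and db/db 4, and 3 after GC correction without db/db 1. Leaving out 1 library gave 5 to 7. Bcat1 and the branched-chain amino acid and inflammatory lists were called under none of 26 alternatives each. Selenbp1 was called under all 25 of its alternatives, from 1.75 to 2.07. GC correction ended the call of 20 of the 22 named genes past the threshold, no filter 19, scaling to equal sums 11 and limma-voom 0. With no filter the log2 changes themselves stayed as they were, and after GC correction those of Gckr, CT025671.2 and Katnal2 hardly moved, while that of Glra3 went from -0.51 to -0.33. No result reversed, direction being compared only where the reported or the alternative result was called. Depth was similar across libraries, and genes below 1 FPKM, such as most cytokines, were not tested.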

Other observations

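The tests of Lepr, of the receptor genes and of the chaperone genes were chosen only after results were seen. The rule for reading the counts of other splits was fixed before. The lists, the fit and the members left out in those counts were not. The genes in this paragraph lie outside the fixed lists and were named after their values were seen. Grm7 and Grm8, group III metabotropic glutamate receptors of retinal synapses, fell by 0.43 and 0.40 (adjusted p = 0.0419 for each, with all 9 libraries). Tacr3, a neurokinin receptor gene, fell by 0.42 (adjusted p = 0.0419). Tnip2, an inhibitor of NF-kB signalling, rose by 0.48 (adjusted p = 0.0337), Irak2, a kinase of the interleukin 1 receptor pathway, by 0.37 (adjusted p = 0.0441), and Csk, a Src-inhibiting kinase, by 0.37 (adjusted p = 0.0419).

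A hypothesis from such falls was that glutamate and GABA receptor genes are lower as a set. After GC correction without db/db 1 the full list of 34 gave a camera p of 0.0139. That list held the 3 genes that had prompted it, Grm7 and Grm8 among them, and the version without them was chosen after this p was seen. It gave p = 0.120, or 0.492 with an estimated correlation, with 18 of 31 members negative, and 29 of 56 splits gave a p as small (the smallest other 1.45e-05). With all 9 libraries it gave p = 1.22e-04 (0.174 with an estimated correlation; 24 of 31 negative), and without db/db 1 p = 0.0551 (0.328). The test leaves the hypothesis open, and chance cannot be excluded.

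A further hypothesis, from the fall of Hsp90b1, was that chaperone genes of the endoplasmic reticulum may be lower as a set in db/db. With Calr, a calcium-binding chaperone gene (-0.52), and Pdia3, a disulfide isomerase gene (-0.49), passing without db/db 1, a list of 29 was drawn up. Without the 3 members seen first, and after GC correction without db/db 1, 5 of 26 fell and 23 were negative, with a median of -0.13 (camera p = 6.45e-06; p = 0.00343 with an estimated correlation; 4.10e-08 for the full list, from which those 3 were left out only after that p was seen). The real split was the 1 of 56 with a p as small, the next being 9.31e-06, but the list and the fit were chosen on the real grouping and not on the others, so this count does not exclude chance. With all 9 libraries the p was 0.0207, or 0.354 with an estimated correlation. The list was chosen and tested on the same samples, so this stays a hypothesis. Nor were the 26 members all unseen, since Ero1l had been named from the hypoxia list. The unfolded protein and integrated stress response list, fixed in advance and tested earlier, shares members with it such as Hsp90b1, Calr, Pdia6, Manf and Creld2. Of these Pdia6, Manf and Creld2 were among the 5 that fell (adjusted p over all genes = 0.0281, 0.0385 and 0.0366). Without db/db 1 and with no GC correction that fixed list was not called (camera adjusted p = 0.666, pointing down). Its median was 0.0071, and 4 of its members fell and 1 rose. The 4 were Hsp90b1, Calr, Pdia6 and Manf, all in the chaperone list too, so neither list backs the other.

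Strain variants near Lepr, carried along with the db mutation, could put many calls on its chromosome. Within 20 Mb of Lepr 21 of 212 genes passed without db/db 1 (9.91%), against 10.6% elsewhere (odds ratio 0.931, two-sided Fisher's exact p = 0.823). That argues against variants in this window as a source of many calls in that fit. The calls of the other fits, and variants outside the window, were not tested.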
